A study of Mus musculus with 2 samples.

How the data were processed

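H3K9me3 was measured by chromatin immunoprecipitation and sequencing of heart tissue from B6NCrl mouse embryos of both sexes at day 16.5, in 1 group of 2 biological replicates numbered in the labels. Per the labels, each replicate was a pool of hearts. The analysis started from 4 deposited peak lists in narrowPeak format on mm10, per the text notes deposited with them. These notes describe the lists as peaks of replicate 1, peaks of replicate 2, peaks of the pooled replicates, and replicated peaks derived from the other 3 lists. Peaks were thus called by the authors per replicate and on the pool. The notes name, besides the replicate's own alignment, 2 other inputs for replicate 1 and 1 other input for replicate 2, which replicate 1 shared. The role of these inputs, the aligner, the peak caller, its threshold and the treatment of the control were not given in the sources used here.

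Each peak's enrichment signal was deposited by the authors as a value whose scale and definition were not given in the sources used here. The −log10 p and −log10 q values of each peak were also deposited by the authors. They and the signal are the authors' own values and were used only to rank or filter peaks within a list. The lowest deposited −log10 p was 2.00 in replicate 1 and in replicate 2, and 52.2% of replicate 1 peaks but 11.5% of replicate 2 peaks had a −log10 q of at least 2. The read depth was unknown, so no counting interval was given for any share. A binomial interval over peaks was used only to set the spread of the pooled shares among the alternatives.

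Coordinates were compared with the reference assembly GRCm38.p6, of which mm10 is the browser name, and genes were taken from the GENCODE M21 annotation. Positions are printed 1-based. Peaks were counted as shared when they overlapped by at least 1 bp. The chance overlap was taken from 1000 circular rotations of a list along each main chromosome, with N bases skipped, and the permutation test was one-sided. Genomic features (1 kb around transcript starts of coding genes, coding-gene exons, sequence outside every annotated gene, soft-masked repeats, GC and CpG content) were compared with 1000 rotations by two-sided tests.

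A gene was counted when its body overlapped a peak. The genes tested were 21919, of which 21911 were protein-coding and 8 were noncoding imprinted genes. The 16 gene lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. The lists were zinc finger genes, olfactory receptors, vomeronasal receptors, clustered protocadherins, major urinary proteins, keratins and keratin-associated proteins, defensins, Hox genes, ribosomal proteins, histone genes, imprinted genes, germline genes, cardiomyocyte genes, other heart cell types, neuronal genes, and hepatic and gut genes. Family lists were defined by gene symbol and the others by name, and Zim1, Rpl10l and H13 each belonged to a family list and a named list. Each count was set against 10000 random lists of the same size matched on deciles of gene length, with a two-sided permutation test and Benjamini-Hochberg adjustment over the 16 lists at a threshold of 0.05. Genes and peaks are not replicates of the experiment, so these tests describe the lists and not the variation between hearts. The position within zinc finger genes was compared with 10000 lists of other genes with a peak, matched on length.

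The alternatives were the pooled list, each replicate's own list, replicated peaks with −log10 q of at least 2, at least 500 bp of gene body under peaks, a peak within 1 kb of a transcript start, and 1000 rotations of list membership along the gene order, which keep tandem clusters together. These rotations do not match on gene length. The definitions by 500 bp and by transcript start were applied to the replicated list only. For the overlap they were 50% of the peak, stricter peaks, the same number of best peaks from both lists, and autosomes alone. After the replicated list was seen to be longer than that of replicate 2, the replicated peaks found in both replicates' own lists were added, as was the stricter list for the X chromosome.

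Named genes were, for each list, up to 4 members with the most base pairs under replicated peaks, and for cardiomyocyte, other heart, ribosomal and Hox genes also the first 4 members without a peak. Genome-wide they were the 20 coding genes with the most base pairs under peaks that also had a peak in both replicates. The 5 peaks of highest signal, the 5 widest, and imprinted genes with a peak within 2 kb of a transcript start could also be named. Peaks on unplaced contigs were left out of the gene, feature and chromosome comparisons.

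The tests were tested on simulated data. For lists of 200 members with no excess, the length-matched test made a call in 2% of simulated lists, and it recovered 97% of those with a 1.5-fold and 100% of those with a 2-fold excess. For lists of 50 members the shares were 3.5%, 44.5% and 83.5%. The gene-order test recovered 63% of 2-fold lists of 200 members, and the position test 97.5% of lists with 75% of peak base pairs beyond the midpoint. In these gene simulations each gene had a peak independently of the others, and calls were made at an unadjusted p under 0.05. The rates therefore do not measure false calls for clustered lists whose members share peaks, nor recovery after adjustment. Computations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.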

Results

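H3K9me3, the trimethylation of lysine 9 on histone H3 and a mark of repressed chromatin, was mapped by chromatin immunoprecipitation and sequencing in the embryonic mouse heart. The tissue came from mixed-sex B6NCrl embryos at day 16.5 of gestation. The design held 1 group of 2 biological replicates, each made from pooled hearts, and replicate 2 was pooled from 41 embryos. The data were 4 peak lists on the mm10 build, namely the peaks of replicate 1, the peaks of replicate 2, the peaks of both replicates pooled, and a list the depositors named replicated peaks. No second tissue, age or treatment was included, so the comparisons were between the replicates and between parts of the genome. The read depth of each replicate was unknown, because a peak list holds no read counts.

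The H3K9me3 regions of the heart recurred between the replicates far above chance, and their strongest regions recurred most. Replicate 2 had 19634 peaks covering 5.58 Mb, and 13366 of them (68.1%) were overlapped by a replicate 1 peak. Replicate 1 had 83187 peaks covering 23.7 Mb, and 13176 of them (15.8%) were overlapped by a replicate 2 peak. The exons of Klf14, a Krüppel-like transcription factor gene, and of Zfp810, a zinc finger gene, held 3 of the 5 peaks of highest signal in the replicated list, and all 3 overlapped a peak in each replicate's own list. Of the 1000 strongest peaks by −log10 p, 96.6% of those in replicate 2 and 81.2% of those in replicate 1 were overlapped by the other replicate.

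On the main chromosomes, circular rotation of the peaks gave a mean overlap of 1.91% for replicate 2 peaks against 67.8% observed, a ratio of 35.5. For replicate 1 peaks it gave 0.454% against 15.7%, a ratio of 34.5. Both had a one-sided permutation p of 0.000999, the smallest that 1000 rotations can give. The lists differed 4.24-fold in number, so the shares depended on how much of each was used. With the same number of best peaks from both lists, 38.1% of replicate 2 peaks and 34.8% of replicate 1 peaks overlapped. For replicate 1 an overlap of 50% of the peak gave 10.2%. Peaks with −log10 q of at least 2 numbered 43445 in replicate 1 and 2255 in replicate 2. Of these, 4.45% of replicate 1 peaks and 85.1% of replicate 2 peaks overlapped. The replicate 1 share was thus limited by the small number of replicate 2 peaks.

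**Figure D1:**
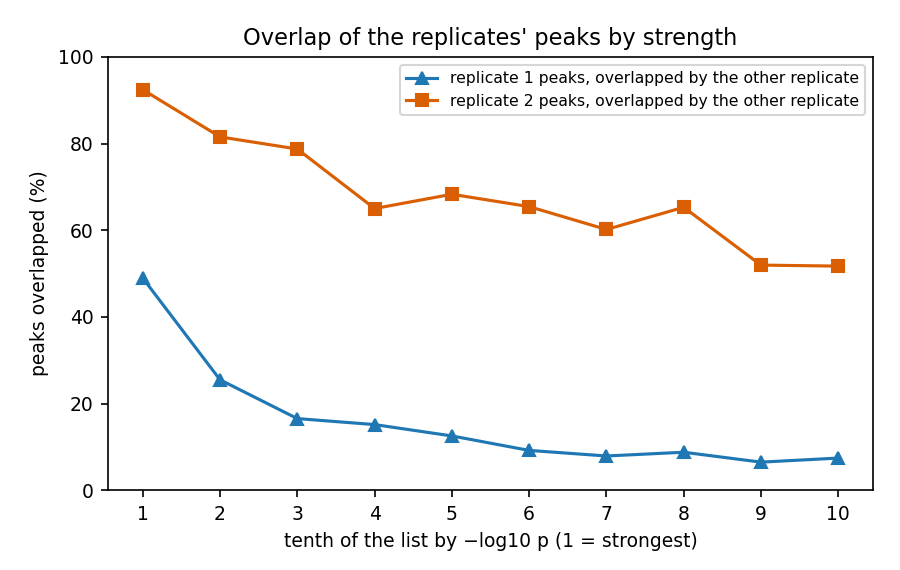
Share of each replicate's peaks (y axis, %) overlapped by at least 1 bp by a peak of the other replicate, in 10 equal segments of the list ranked on the depositors' −log10 p (x axis, strongest first). Triangles are replicate 1 peaks and squares are replicate 2 peaks; the share was 49.0% in the strongest and 7.42% in the weakest segment of replicate 1, and 92.5% and 51.7% in replicate 2.

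Within each replicate, the peaks that recurred had higher signal than those that did not. Recurring replicate 1 peaks lay at a median signal percentile of 74.9, and the others at 43.3. In replicate 2 the percentiles were 58.2 and 42.6, so the difference was 31.6 points in replicate 1 and 15.6 points in replicate 2. Recurring peaks were also wider, with a median of 346 bp against 221 bp in replicate 1 and 256 bp against 210 bp in replicate 2. These values describe each list by itself, and the difference in replicate 2 was smaller than that in replicate 1 by more than 1.5 times.

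The replicated list, used below for genes and regions, held 33552 peaks covering 12951260 bp, or 0.483% of the genome, with a median width of 319 bp. Every replicated peak had the coordinates of a pooled peak, and 63.7% of the 52636 pooled peaks were kept. Of the pooled peaks, 12244 (23.3%) overlapped a peak in both replicates' own lists by 50% of either peak, and all 12244 were kept. The replicated list also kept 58.1% of the pooled peaks found in replicate 1 only, 53.7% of those found in replicate 2 only and 30.0% of those found in neither. Peaks in both replicates' own lists therefore made up 36.5% of the replicated list, and 21308 replicated peaks (63.5%) were not in both. Among pooled peaks with −log10 q of at least 2, the share in both replicates was 47.7%, and 88.3% were kept.

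Zinc finger genes, a large family of sequence-specific DNA-binding proteins that includes the KRAB repressors, carried H3K9me3 more often than other genes of their length. Of 421 members, 172 overlapped a replicated peak, against 74.4 in length-matched random lists (95% range 61 to 89), a 2.31-fold excess. Zfp110 had 12666 bp, or 80.1% of its gene body, under 11 peaks, and Zfp873 had 71.2% of its gene body under 14 peaks. Zfp981 had 10842 bp under peaks, and Zfp68 had 9299 bp, including a peak of signal 12.9 on chromosome 5 from 138605052 to 138607859 that overlapped exons. All 4 genes had peaks in both replicates.

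The two-sided permutation test over 10000 length-matched lists gave p = 0.0002 for the zinc finger genes, the smallest that 10000 lists can give, and an adjusted p of 0.00064 after Benjamini-Hochberg adjustment over 16 lists. The excess was 2.98-fold in replicate 2's own list, with 155 members, and 1.90-fold in replicate 1's own list, with 230 members. With at least 500 bp of the gene body required under peaks it was 3.57-fold, with 136 members.

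**Figure D2:**
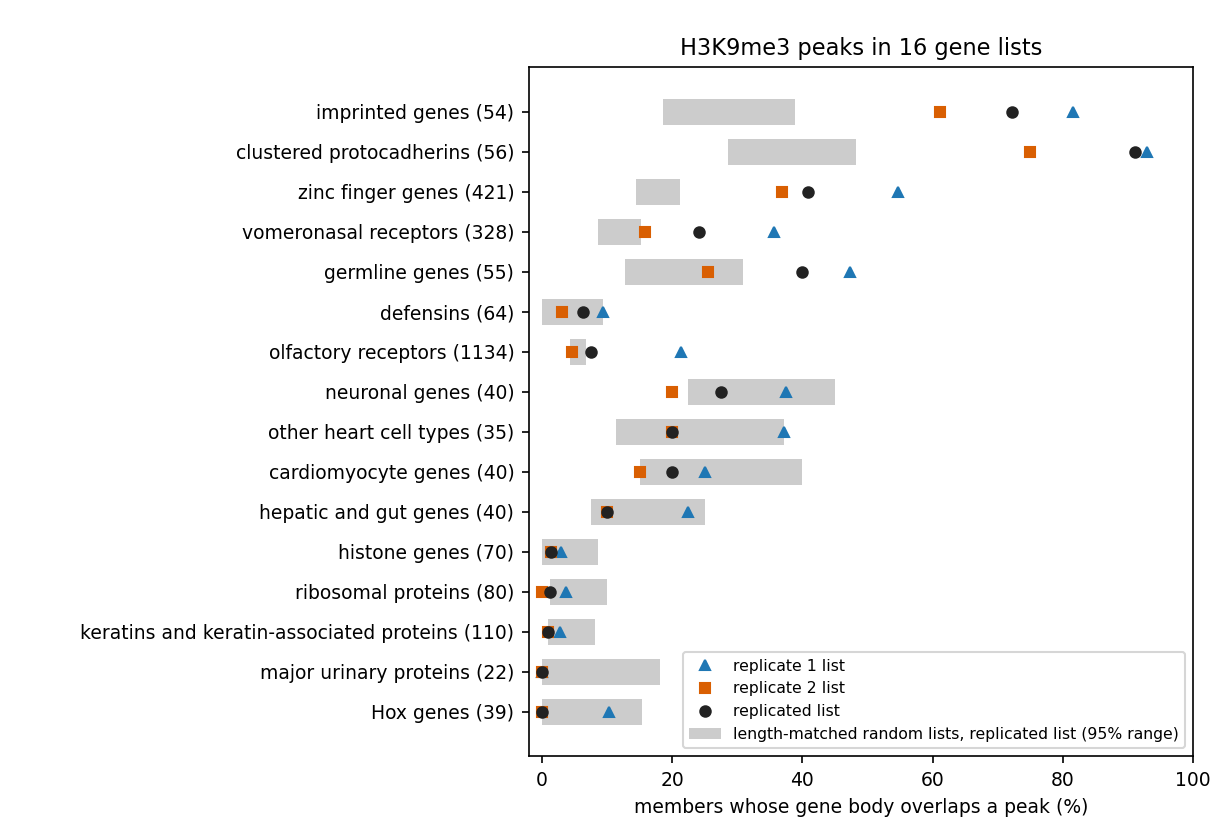
Share of members whose gene body overlaps an H3K9me3 peak (x axis, %) in 16 gene lists (y axis, number of members in brackets). Circles are the replicated list, triangles replicate 1, squares replicate 2, and grey bars the 95% range of length-matched random lists for the replicated list. The circles of imprinted genes (72.2%), clustered protocadherins (91.1%) and zinc finger genes (40.9%) lie above their bars, which apply to the circles.

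Within zinc finger genes, the mark lay toward the 3′ end, where this family encodes its finger arrays. Of the 386423 bp under replicated peaks in the 172 genes, 77.2% lay beyond the midpoint of the gene, against 53.9% in other genes with a peak matched on length (95% range 42.6 to 63.5). The last exon held 44.5% of these base pairs, against 12.8% in the matched genes (95% range 7.29 to 18.7). Last exons took a median of 15.2% of the zinc finger genes with a peak but 2.10% of other genes with a peak. With other genes matched on that share instead, the comparison rose to 23.6% (95% range 14.4 to 31.96). Along the gene body, the share of peak base pairs went from 1.11% in the first of 10 equal segments to 22.1% in the last, whereas other genes had 10.6% and 10.5%. In Zfp110, a peak of 6134 bp on chromosome 7 from 12844001 to 12850134 ran across exons 5 to 7 and into exon 8, the last exon, which lies from 12848397 to 12850577. Peaks covered 80.1% of this gene, so it does not by itself show the lean of the list. Of its peak base pairs, 58.3% lay beyond the midpoint and 15.3% in the last exon. The last exon share was 13.3% in Zfp873, 0% in Zfp981 and 32.4% in Zfp68, each below that of the list.

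For both measures the two-sided permutation p was 0.0002, the smallest that 10000 lists can give. The share beyond the midpoint was 74.9% in replicate 1 and 81.3% in replicate 2, and the last exon share was 40.0% and 53.1%.

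**Figure D3:**
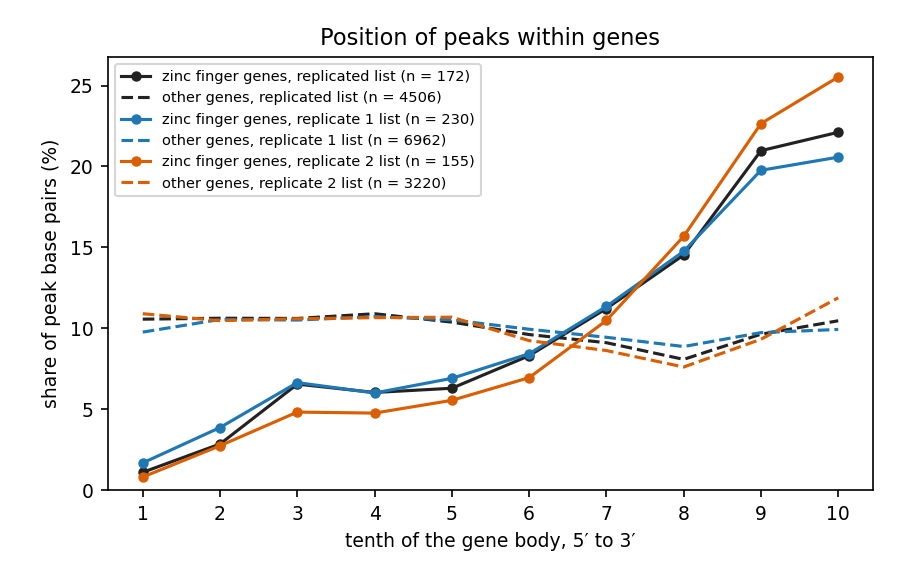
Position of H3K9me3 peaks along gene bodies. The x axis divides the gene body into 10 equal segments from 5′ to 3′ and the y axis the share of peak base pairs (%); solid lines are zinc finger genes and dashed lines other genes with a peak, in black for the replicated list, blue for replicate 1 and orange for replicate 2. Zinc finger genes reach 22.1% in the last segment of the replicated list, 20.6% in replicate 1 and 25.5% in replicate 2, and the dashed line of the replicated list starts at 10.6% and ends at 10.5%.

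**Figure D4:**
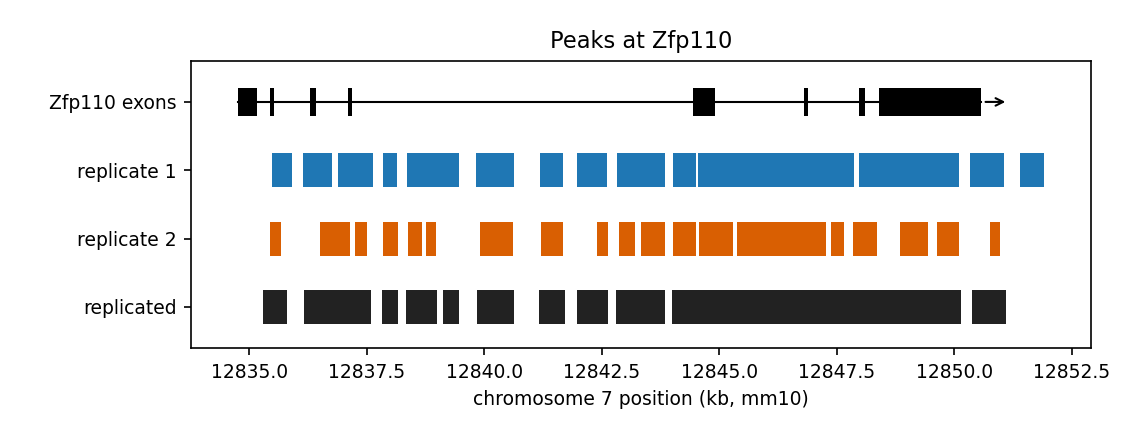
Map of Zfp110 on chromosome 7 (x axis, kb, mm10), with its exons from the annotation (top, transcribed to the right) and the peaks of replicate 1, replicate 2 and the replicated list (y axis). The widest bar of the replicated list spans 6134 bp at the 3′ part of the gene, where both replicates also have peaks. Replicated peaks cover 80.1% of the gene body.

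The clustered protocadherins, neuronal cell adhesion proteins encoded in tandem on chromosome 18, had the highest share of members with H3K9me3 among the lists. Of 56 members, 51 overlapped a replicated peak, against 21.6 in length-matched lists (95% range 16 to 27), a 2.36-fold excess with an adjusted permutation p of 0.00064. Peaks within 1 kb of a transcript start were present at 38 members, 14.8-fold above matched lists. Pcdhga1 had 45597 bp under 82 peaks, Pcdhga2 had 44452 bp, Pcdhga3 had 42801 bp and Pcdhgb1 had 41493 bp. The window from 37 to 38 Mb of chromosome 18 had the most base pairs under replicated peaks of 2737 windows of 1 Mb, at 90059 bp. Of the 20 protein-coding genes with the most covered base pairs, 14 belonged to the gamma cluster, and Gm42416, Gm37013 and Gm37388 were gene models that ran into it.

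The gamma protocadherin genes overlap each other, and their widest peak, of 3007 bp on chromosome 18 from 37755570 to 37758576 and intronic in Pcdhga1, was counted in each gene that contains it. When list membership was rotated along the gene order, which keeps clusters together, the excess was 4.24-fold with an adjusted permutation p of 0.00533. That rotation does not match on gene length, so the higher ratio can also reflect these long gene bodies. No test accounted for clusters and length together.

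Imprinted genes, expressed from the maternal or the paternal copy, carried H3K9me3 at their transcript starts. Of 54 members, 39 overlapped a replicated peak, against 15.4 in length-matched lists (95% range 10 to 21), a 2.53-fold excess with an adjusted permutation p of 0.00064. A peak lay within 1 kb of a transcript start at 29 members, 12.5-fold above matched lists. Some peaks were counted for neighbouring members, such as Nnat and Blcap or Peg3 and Usp29, so the members are not independent loci. When list membership was rotated along the gene order, which keeps neighbours together, the excess was 3.39-fold with an adjusted permutation p of 0.00533. That rotation does not match on gene length, and no test accounted for neighbours and length together. Gnas, which encodes a stimulatory G protein subunit, had 7873 bp under 4 peaks, the widest on chromosome 2 from 174297847 to 174300713 over exonic sequence and a transcript start. Mest, a paternally expressed gene, had 4675 bp, Grb10, an adaptor protein that restrains growth, had 4730 bp, and Trappc9 had 5207 bp. The Trappc9 intron peak on chromosome 15 from 72808208 to 72810098 was also the exonic peak of Peg13, a noncoding RNA gene.

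At several imprinted loci a peak lay over a transcript start. At Nnat, a small paternally expressed gene inside an intron of Blcap, a peak of signal 8.06 covered a start of each gene on chromosome 2 from 157559102 to 157560633. At Peg3 and Usp29, which start beside each other, a peak of 1391 bp lay over both starts on chromosome 7 from 6729433 to 6730823. The start shared by Snrpn and Snurf was covered from 60004624 to 60005202 on chromosome 7, and the start of Airn, a noncoding RNA antisense to Igf2r, from 12741175 to 12743034 on chromosome 17. Cdkn1c, a maternally expressed cell cycle inhibitor gene, had a peak over its start on chromosome 7 from 143459813 to 143461040, and a peak on chromosome 11 from 22971766 to 22973112 covered starts of both Commd1 and Zrsr1. At Meg3, a maternally expressed noncoding RNA gene, a peak lay 319 bp from a start, on chromosome 12 from 109542587 to 109543133. Kcnq1ot1, a noncoding RNA antisense to Kcnq1, had 2144 bp under 2 peaks, with a peak within 1 kb of its start and the widest inside the transcript, from 143250266 to 143251396 on chromosome 7. H19 had no peak in its gene body, and a peak of 990 bp lay 1801 bp from its start, on chromosome 7 from 142579944 to 142580933. All of these peaks overlapped a peak in each replicate's own list.

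Germline genes, which act in meiosis, the piRNA pathway or gametes, carried the mark, often at their transcript starts. Of 55 members, 22 overlapped a replicated peak, against 11.6 in length-matched lists (95% range 7 to 17), a 1.90-fold excess with an adjusted permutation p of 0.00064. At 15 members a peak lay within 1 kb of a transcript start, 6.96-fold above matched lists. This count was made in the replicated list only, and not in either replicate's own list or in peaks of both. Taf7l, a testis-expressed subunit of the basal transcription machinery, had a peak over its start on the X chromosome from 134474769 to 134476573. Meioc, needed for meiosis, had a peak over its start on chromosome 11 from 102664986 to 102666388. Tdrd9 and Mov10l1, helicases of the piRNA pathway, had 1687 bp and 1088 bp under peaks. The gene body excess was not past the threshold in either replicate's own list, at 1.40-fold in replicate 1 (adjusted permutation p = 0.0501) and 1.72-fold in replicate 2 (adjusted permutation p = 0.106). It also ended with at least 500 bp under peaks (1.64-fold, adjusted permutation p = 0.416) and with peaks in both replicates' own lists (1.43-fold, adjusted permutation p = 0.763).

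Chemosensory receptor genes, which lie in large tandem clusters and serve the nose, exceeded length-matched genes in the replicated list. Vomeronasal receptors had a peak in 79 of 328 members, against 38.4 expected (95% range 28 to 50), a 2.06-fold excess with an adjusted permutation p of 0.00064. Vmn2r102 had 3146 bp under peaks, Vmn2r16 had 3079 bp, Vmn2r53 had 2976 bp and Vmn2r61 had 2622 bp. Olfactory receptors had a peak in 86 of 1134 members, against 62.3 expected (95% range 49 to 77), a 1.38-fold excess with an adjusted permutation p of 0.00853. Olfr398, Olfr1349, Olfr139 and Olfr1347 were the most covered, with 3381 bp, 3144 bp, 2202 bp and 1932 bp.

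Neither receptor list passed every definition. The vomeronasal excess was 1.60-fold for peaks near a transcript start (adjusted permutation p = 0.185) and 1.14-fold with membership rotated along the gene order (adjusted permutation p = 0.591). The rotation does not match on gene length, so its ratios for both receptor lists can also reflect the lengths of these genes. The olfactory receptors fell below the rotated gene order, at 0.353-fold (adjusted permutation p = 0.00533), and their excess over length-matched lists was lost in replicate 2's own list (1.27-fold, adjusted permutation p = 0.202), with −log10 q of at least 2 (1.16-fold, p = 0.512), with 500 bp under peaks (1.09-fold, p = 0.876) and with peaks in both replicates' own lists (0.933-fold, p = 1), all adjusted permutation p-values.

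Genes expressed in the heart did not pass the test against length-matched genes. Of 40 cardiomyocyte genes, 8 overlapped a replicated peak, against 10.8 in length-matched lists (95% range 6 to 16; 0.740-fold, adjusted permutation p = 0.546). A peak within 1 kb of a transcript start was present at 0 of them (adjusted permutation p = 0.660). As 0 is the lowest count possible, a deficit at starts could not have been called. Over gene bodies, the cardiomyocyte ratio was 0.620 in replicate 1's own list, close to the threshold (adjusted permutation p = 0.0504). It was 0.759 in replicate 2's own list (adjusted permutation p = 0.798). Myh6 and Myh7, the cardiac myosin heavy chains, and Tnnt2 and Tnni3, the cardiac troponins, had no peak in the replicated list or in either replicate's own list. Kcnq1, a potassium channel gene, had 3431 bp under peaks, among them the peak inside Kcnq1ot1. Scn5a, the cardiac sodium channel gene, had 1321 bp, Gja5, a gap junction gene, 808 bp and Ttn, which encodes titin, 708 bp, in long gene bodies. Gja5 had no base pair under peaks in replicate 2's own list.

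Markers of the other cell types of the heart, such as endothelium, epicardium, fibroblasts, smooth muscle and blood, had a peak in 7 of 35 members against 8.57 expected (0.817-fold, adjusted permutation p = 0.655). Near a transcript start 0 had a peak (adjusted permutation p = 0.725), and a deficit there could not have been called either. Flt1, a vascular growth factor receptor, had 2201 bp under peaks, Npr3, the natriuretic peptide clearance receptor, 1158 bp, Myh11, the smooth muscle myosin, 1108 bp and Pdgfrb, a mural cell receptor, 1051 bp. The endothelial genes Cdh5 and Tie1 had no peak in the replicated list or in either replicate's own list, and Kdr and Emcn had 215 bp and 309 bp in replicate 1 only. The ratio of this list lay above 1 with 500 bp required (1.50), in replicate 2 (1.15) and with peaks in both replicates' own lists (1.48), none past the threshold.

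Genes of other organs did not pass the test either. Neuronal genes had a peak in 11 of 40 members (27.5%) against 32.5% expected (adjusted permutation p = 0.581), led by Slc17a7, a vesicular glutamate transporter, with 3763 bp, Grin2b, a glutamate receptor subunit, with 3720 bp, Cntnap2 with 1902 bp and Nrxn1 with 1704 bp. The Slc17a7 peak, on chromosome 7 from 45168964 to 45172316, covered a transcript start and overlapped a peak in each replicate's own list. Hepatic and gut genes had a peak in 4 of 40 members against 6.23 expected (adjusted permutation p = 0.564), namely Cyp3a11, a drug-metabolizing cytochrome, with 1158 bp, Lgr5, an intestinal stem cell receptor, with 1016 bp, the transcription factor gene Hnf1a with 539 bp and Trf, the transferrin gene, with 194 bp. The neuronal ratio was 1.72 near transcript starts and 1.32 along the gene order, and the hepatic and gut ratio was 1.41 near transcript starts, none past the threshold.

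Other tandem families and housekeeping genes also did not pass the test against length-matched lists. Hox genes, the developmental patterning clusters, had 0 of 39 members with a replicated peak in the gene body, including Hoxa1, Hoxa10, Hoxa11 and Hoxa13 (2.74 expected, adjusted permutation p = 0.210). In replicate 1's own list 4 Hox genes had a peak, Hoxa7, Hoxc13, Hoxd3 and Hoxd12 (0.799-fold, adjusted permutation p = 0.906), and a replicated peak lay within 1 kb of a start of Hoxd10, and these 5 genes were named after their values were seen. The major urinary proteins, liver-secreted pheromone carriers, had 0 of 22 (1.28 expected, adjusted permutation p = 0.581). For these proteins and the Hox genes 0 is the lowest count possible, so the length-matched test could not have called a deficit. Keratins and keratin-associated proteins had 1 of 110, Krtap22-2 (4.77 expected, adjusted permutation p = 0.196). Defensins, epithelial antimicrobial peptides, had 4 of 64, Defb22, Defb4, Defb39 and Defb33 (2.64 expected, adjusted permutation p = 0.581). Ribosomal proteins had 1 of 80, Rpl10l, a testis-expressed copy that the germline list also held, and Rpl10, Rpl10a, Rpl11 and Rpl12 had none (3.59 expected, adjusted permutation p = 0.423). Histone genes had 1 of 70, H13 (2.60 expected, adjusted permutation p = 0.581), whose symbol matched the pattern although it encodes a signal peptide peptidase and was also in the imprinted list.

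Against rotation along the gene order, all 6 of these lists lay below expectation and 4 passed the threshold. The ratio was 0 for Hox genes (adjusted permutation p = 0.0142), 0.0431 for keratins (adjusted permutation p = 0.00533), 0.0585 for ribosomal proteins (adjusted permutation p = 0.00533) and 0.0680 for histone genes (adjusted permutation p = 0.0142). The Hox call was lost in replicate 1's own list (0.315-fold, adjusted permutation p = 0.0575), and the Hox and histone calls were lost with peaks in both replicates' own lists (0 and 0.121, adjusted permutation p = 0.128 for each). The major urinary proteins (0 against 4.91 expected, adjusted permutation p = 0.234) and the defensins (0.289-fold, adjusted permutation p = 0.150) did not pass. That test does not match on length. Against length-matched lists the defensin ratio was 0.614 with −log10 q of at least 2, and 0 with 500 bp or with peaks in both replicates' own lists, none past the threshold.

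Across the genome, most bases under peaks lay outside genes, as does 54.0% of the genome itself. The peak bases were richer in exonic and in guanine and cytosine sequence than rotated peaks. Of the base pairs under replicated peaks, 55.8% were intergenic against 51.5% after rotation, 5.40% lay in coding-gene exons against 3.95%, and 3.25% lay within 1 kb of a transcript start against 4.05%. Repeats marked in the reference made up 29.5% against 33.8%, and the GC content was 46.3% against 42.0%. Each had a two-sided permutation p of 0.002, the smallest that 1000 rotations can give. The rotations skipped only N bases, so rotated peaks could fall in repeats where reads cannot be placed uniquely. The lower repeat share therefore need not mean less of the mark at repeats. Whether this, or a GC bias of sequencing, moved the repeat and GC shares was not tested. Of the 12783562 bp under replicated peaks on the main chromosomes, 171943 bp were in the last exons of the 172 zinc finger genes with a peak. The exon excess is therefore not separate from the zinc finger result above, and the exon share without these genes was not computed. The promoter deficit was lost in replicate 2 (3.81%, permutation p = 0.438), with −log10 q of at least 2 (3.69%, p = 0.164) and with peaks in both replicates' own lists (4.06%, p = 0.995). The intergenic excess was lost in those latter sets (52.5%, p = 0.366 and 0.420), and the exon excess was lost in replicate 1 (4.11%, p = 0.176), all by the same permutation test.

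Of the 5 widest replicated peaks, 1 lay on an unlocalized contig and the others on the main chromosomes. The widest, 8642 bp on chromosome 1 from 88225406 to 88234047, overlapped exons of Mroh2a, whose gene body had 25208 bp under peaks. The next, of 7509 bp on chromosome 17 from 13211552 to 13219060, lay outside genes and 2127 bp from Smok2a, a sperm motility kinase gene. A peak of 5337 bp on chromosome 15 from 76172906 to 76178242 overlapped exons of Plec, the plectin gene. By signal, the first was the Klf14 peak on chromosome 6 from 30956178 to 30958812 (signal 17.4), and the Zfp810 peaks lay on chromosome 9 from 22276779 to 22277951 and from 22278135 to 22279756. A peak on chromosome Y from 259038 to 259472 was far from any coding gene, with Zfy1 the nearest at 465655 bp. Each of these peaks overlapped a peak in each replicate's own list. Tmem132d on chromosome 5, with 40429 bp under 108 peaks, was the most covered gene outside the protocadherin locus.

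Chromosome 7 had the highest density of H3K9me3, with 9265 bp under replicated peaks per Mb, and chromosome 14 the lowest among autosomes, with 3278 bp per Mb. The X chromosome had 1678 bp per Mb against 5219 bp per Mb over the autosomes, a ratio of 0.322. The ratio was 0.394 in replicate 1 and 0.488 in replicate 2, so X was below the autosomes in both, and it was 0.213 for replicated peaks with −log10 q of at least 2. The tissue was of mixed sex, and the number of X copies was not accounted for. Repeats marked in the reference made up 46.8% of X against 35.8% of chromosome 3, the highest among autosomes. The ratio describes called peaks and not the level of the mark on X. Among the 100 windows of 1 Mb with the most covered base pairs, 33 held a zinc finger gene, against 7.27% of all 2737 windows. No test was run on chromosomes, which are not replicates.

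**Figure D5:**
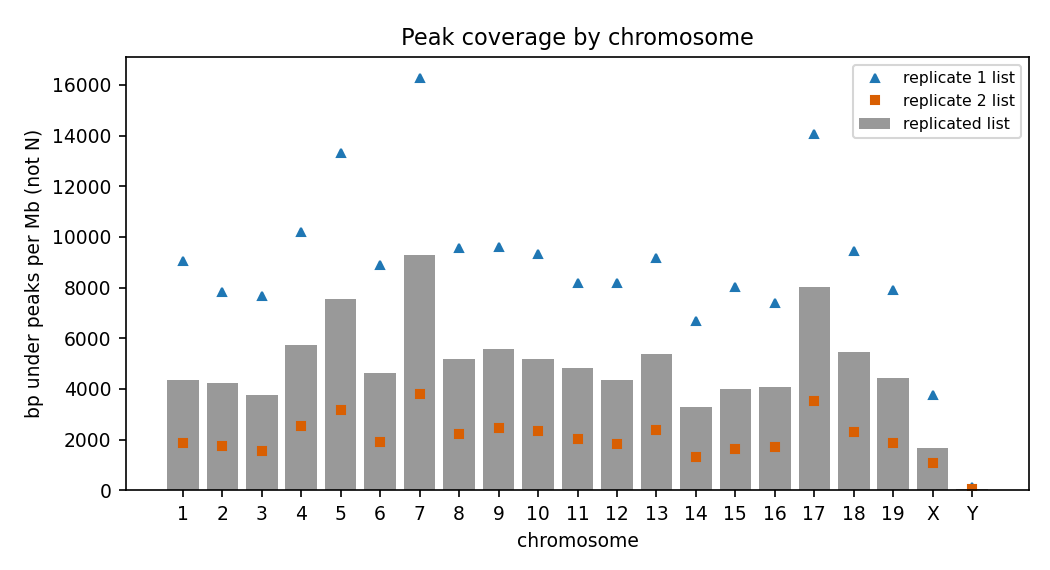
Base pairs under H3K9me3 peaks per Mb of sequence (y axis, N bases left out) on each chromosome (x axis). Bars are the replicated list, triangles replicate 1 and squares replicate 2; the bar is highest on chromosome 7 (9265 bp per Mb) and the X bar is at 1678 bp per Mb.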

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

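The tests of the inputs to peak calling, of membership in both replicates' own lists and of a further way into the replicated list were chosen only after the result was seen. The design held 1 group, so no biological explanation was tested for any pattern here.

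A signal lay in sequence outside the comparisons by gene, feature and chromosome: 243 replicated peaks were on 20 of the 44 unplaced or unlocalized contigs. These contigs hold 5.25 Mb, and their peak density was 6.11-fold that of the autosomes in the replicated list, 3.40-fold in replicate 1 and 9.21-fold in replicate 2. A peak of 5301 bp on contig 4_GL456216_random was among the 5 widest and the 5 of highest signal.

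Replicate 1 had 4.24-fold as many peaks as replicate 2. The 62263 replicate 1 peaks with no replicate 2 peak within 1 kb followed replicate 2's own peaks over 2399 autosomal windows of 1 Mb (Spearman rho 0.564, highest of the rotated values 0.322, one-sided permutation p = 0.000999, the smallest that 1000 rotations can give), across windows that are not independent. Rotated peaks stayed below that value, so many of the additional peaks may be weak enrichment that was called in replicate 1 alone. The notes name 1 more input for replicate 1 than for replicate 2, and its effect and that of depth cannot be told apart, because no list called with equal inputs or known depths was analysed here. A real difference between the pools of hearts also stays open.

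The replicated list was 1.71-fold as long as replicate 2's own list. The tables argue against a requirement for a peak in both replicates' own lists, since 63.5% of replicated peaks lacked it. They also argue against selection by strength alone, since among the 40392 pooled peaks not in both lists, −log10 p separated kept from dropped peaks with an area under the curve of 0.719. Of the 7127 pooled peaks in neither replicate's list, 30.0% were kept, although the notes name the pooled list and the lists of both replicates as inputs and no other list, so how these peaks entered cannot be told apart.

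Peaks in zinc finger genes lay in last exons, which held 44.5% of their peak base pairs. Long last exons alone are argued against, because other genes matched on the share of the gene taken by the last exon had 23.6% (95% range 14.4 to 31.96), and matching also on last exon GC content gave 23.8% (95% range 14.7 to 31.7). Reads shared between similar genes on the main chromosomes are argued against as well. Of the 32-base words under these peaks, 96.6% occurred once on the main chromosomes, compared with 85.6% in the parts of the same exons not under peaks. Copies on unplaced or unlocalized contigs were not searched. These, copies collapsed in the reference, and biases of the input shared by both replicates were not tested and stay open.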

How the results depend on the processing

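The peaks found in both replicates' own lists, and the stricter list for the X chromosome, were chosen only after the result was seen. Of 173 alternatives over 27 results, 134 kept the direction and the side of the threshold, 15 lost the call, 4 gained one, 13 reversed and 7 moved by more than their spread. For 9 results every alternative was the same, namely both replicate overlaps (38.1% to 85.1% and 4.45% to 34.8%), the zinc finger (1.90 to 3.57), protocadherin (1.81 to 14.8), imprinted (1.95 to 12.5), cardiomyocyte (0 to 0.944) and major urinary protein (0) lists, the zinc finger position and the soft-masked share (28.4% to 29.7%). For the major urinary proteins 0 of 22 members is the lowest count possible and passed no threshold, so it says nothing about stability. Every alternative of the soft-masked share used the same rotation, which skipped only N bases. The cause of each change was not tested. No paired analysis was possible because the design holds 1 group. Depth was unknown, so its effect was not measured.

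Values moved for pooled peaks in both replicates (23.9% with 1 bp, 47.7% with −log10 q of at least 2), pooled peaks kept (88.3% at that q), the signal difference (15.6 without replicate 1) and the X ratio (0.394 to 0.488 leaving out a replicate, 0.213 at that q). For the pooled shares the spread came from a binomial interval over peaks, which are not replicates, so small differences counted as moved. For the signal difference and the X ratio it was the standard deviation of the replicates' own values. The signal difference of replicate 2 therefore had to count as moved. Ratios and adjusted permutation p-values of the lists follow, and those along the gene order were not matched on gene length. With 500 bp required they were 1.09 (0.876) for olfactory, 1.64 (0.416) for germline, 0 for defensin, 1.10 for histone and 1.50 for other heart genes. Along the gene order they were 0.353 (0.00533) for olfactory, 1.14 (0.591) for vomeronasal, 0.0431 (0.00533) for keratin, 0.289 for defensin, 0 (0.0142) for Hox, 0.0585 (0.00533) for ribosomal, 0.0680 (0.0142) for histone and 1.32 for neuronal genes. Near transcript starts they were 1.60 (0.185) for vomeronasal, 1.72 for neuronal and 1.41 for hepatic and gut genes.

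With −log10 q of at least 2 they were 1.16 (0.512) for olfactory and 0.614 for defensin genes, the promoter share was 3.69% (0.164) and the intergenic share 52.5% (0.366). With peaks in both replicates' own lists they were 0.933 (1) for olfactory, 1.43 (0.763) for germline, 0 for defensin and 1.48 for other heart genes, the promoter share was 4.06% (0.995) and the intergenic share 52.5% (0.420). Leaving out a replicate gave 1.27 to 1.87 for olfactory, 1.40 to 1.72 for germline, 0 to 0.799 for Hox and 0.979 to 1.15 for other heart genes, a promoter share of 2.65% to 3.81% and an exon share of 4.11% to 6.71%.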

Other observations

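The finer test of gene families, the tests of gene lists for peaks of replicate 1 alone and the windows and families named here were chosen only after the result was seen.

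Peaks found in replicate 1 alone, with none in replicate 2 within 1 kb, exceeded length-matched lists in several gene groups. They were present in 172 of 421 zinc finger genes (1.68-fold over length-matched lists), 226 of 1134 olfactory receptors (2.12-fold), 111 of 328 vomeronasal receptors (1.99-fold) and 44 of 56 clustered protocadherins (1.63-fold), each with an adjusted permutation p of 0.0008. Imprinted genes had them in 29 of 54 members (1.43-fold, adjusted permutation p = 0.00832) and keratins in 1 of 110 (0.136-fold, adjusted permutation p = 0.0229). With membership rotated along the gene order, which keeps tandem clusters together but does not match on gene length, the olfactory receptors fell below expectation (0.687-fold, adjusted permutation p = 0.00639) and the vomeronasal receptors did not pass (1.18-fold, adjusted permutation p = 0.333). In that test zinc finger genes (1.42-fold) and clustered protocadherins (2.73-fold), each with an adjusted permutation p of 0.00639, and imprinted genes (1.86-fold, adjusted permutation p = 0.00913) stayed above expectation and keratins below it (0.0318-fold, adjusted permutation p = 0.00639), and ribosomal protein (0.130-fold, adjusted permutation p = 0.00639) and histone genes (0.0499-fold, adjusted permutation p = 0.00913) also lay below. Germline genes, at 20 of 55, were not past the threshold in either test (1.23-fold over length-matched lists, adjusted permutation p = 0.443, and 1.27-fold along the gene order, adjusted permutation p = 0.333). Over 2737 windows of 1 Mb the base pairs under peaks of the replicates had a Spearman rho of 0.842 and a Pearson r of 0.883, across windows that are not independent.

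Windows dense in H3K9me3 with 0 genes of the 16 lists included 33 to 34 Mb and 17 to 18 Mb of chromosome 7, with 66311 bp and 60958 bp under replicated peaks. The window from 12 to 13 Mb of chromosome 7 had 67470 bp and held 9 zinc finger genes and 12 vomeronasal receptors. The window from 114 to 115 Mb of chromosome 12 had 51267 bp and 0 protein-coding genes, and lies in the immunoglobulin heavy chain variable region. Each of these windows ranked among the 10 densest in replicate 1 and in replicate 2.

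A hypothesis was that peaks at germline gene starts follow the GC content of those promoters. Matching other genes on GC content within 1 kb of the start gave 2.11 genes with a peak (95% range 0 to 5) against 15 observed among 55 germline genes, with a two-sided permutation p of 0.0002, the smallest that 10000 lists can give. Promoter GC content alone therefore did not account for the count in the replicated list, the only list in which this was tested. DNA methylation, which these lists do not measure, was not tested.

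A further hypothesis was that other symbol families carry the mark together. Of 246 families with at least 10 members outside the fixed lists, 0 exceeded chance in both the length-matched and the gene-order permutation test after Benjamini-Hochberg adjustment, and 3 did at an unadjusted p under 0.05. With 100000 matched lists and every rotation of the gene order the number was again 0, with 3 unadjusted. These 3 were Nlrp genes, innate immune and oocyte factors, with a peak in 11 of 17 members (4.93 expected by length), Skint genes, with 9 of 11 (4.44 expected), and Ttll genes, tubulin-modifying enzymes, with 8 of 13 (4.29 expected). The gene-order test, which does not match on length, was passed by 11 families, and none of them passed the length-matched test. They were Arhgap, Cacna, Col, Dnah, Pde, Dock, Galnt, Nlrp, Cfap, Myo and St, with adjusted permutation p-values from 0.00449 to 0.0347, and Nlrp was at 0.0140 there and at 0.318 by length. Secretoglobins (Scgb) had 9 of 34 members with a peak against 1.12 expected (adjusted permutation p = 0.00492 by length), but did not pass the gene-order test (adjusted permutation p = 0.969).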
